A study of Mus musculus with 28 samples.

How the data were processed

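RNA was measured by sequencing in the CA1 field of the hippocampus, the field that carries the output of the hippocampal circuit, from mice carrying the CamkIIδC transgene and from wildtype littermates. CamkIIδC is an isoform of a calcium and calmodulin dependent kinase. As background, mice of this kind are known as a model of heart failure in which the kinase is produced in heart muscle. Transgenic mice drank water with vehicle or with vorinostat, an inhibitor of histone deacetylases also called SAHA, and wildtype mice drank vehicle. Treatment began at 2 months of age and ran for 4 weeks, so tissue came from mice 3 months old, per the labels. Polyadenylated RNA was made into libraries with a TruSeq RNA v2 kit, which does not keep the strand, and sequenced as 50 bp single-end reads on a HiSeq2000.

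The groups were taken from the sample titles: 10 wildtype vehicle, 9 transgenic vehicle and 9 transgenic vorinostat libraries. Wildtype mice given vorinostat were not analysed here, so the effect of the drug without the transgene could not be estimated. Both sexes were used, per the labels, and the sex of each mouse was not given in the sources used here. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these samples, which may in part be technical. No sequencing batch was given in the sources used here.

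The authors deposited whole-number read counts per gene for each library. Per the submitters' processing notes, FastQC 0.11.5, STAR 2.5.2b and featureCounts of Subread 1.5.1 were used with the mm10 genome. The annotation release, the strand setting and the treatment of reads matching several genes were not given in the sources used here. Genes with near-identical copies, such as the hemoglobin genes Hba-a1, Hbb-bs and Hbb-bt, and genes that overlap others therefore have uncertain counts.

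The authors also deposited a table of adjusted expression values for 18014 genes, on a log scale that was read as log2 and that ranged from -13.3 to 18.3. It came from a mixed linear model, per the file name, with terms, software and log base not given in the sources used here. The slope of its gene means on log2 CPM was 0.80 across genes, so its differences are printed in the table's own log units. A second deposited table gave 14 coexpression modules, with each gene's module membership score, a correlation, and the deposited p-value of that score. The membership p-values matched correlations over 30 samples, while 28 libraries were used here.

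All 48709 gene identifiers of the count files were kept for library totals, and 48349 of them (99.3%) were matched to a symbol. Coordinates are from the GENCODE annotation of GRCm38, the assembly also called mm10. Totals per library ran from 20230085 to 33191857 counts, with a median of 23807060.5. The 117 pairs of libraries within groups were compared by a chi-square of their counts per degree of freedom, which ran from 3.37 to 87.4, and 0 files were identical, so no library was merged with another.

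Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, robust fitting and 1 fit over all 28 libraries, and 3 contrasts were taken from it. The low-count filter of edgeR, with a minimum count of 10 and a minimum total of 15, left 17009 genes. Adjusted p-values are by Benjamini and Hochberg over these genes within a contrast, with a threshold of 0.05. Standard errors were derived from the log2 fold change and the F statistic. The median standard error of a log2 fold change was 0.0862, 0.0885 and 0.0864 for transgenic vehicle against wildtype vehicle, vorinostat against transgenic vehicle and vorinostat against wildtype vehicle. CPM denotes a gene's counts scaled to the TMM-adjusted library total in the usual way, given as mean ± SD. Summed hemoglobin, Xist, and Alas2 in its ratio to hemoglobin were instead scaled to the library total without TMM.

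Before the data were examined, 35 gene lists were fixed, 17 of pathways and 18 of cell types that CA1 or neighbouring tissue could hold. They were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over all 105 tests. Two-sided exact permutation tests of a list's mean log2 CPM per library were added after seeing the data, with a prior count of 2 in the log. Members of a list are also reported adjusted over the list alone. The pathway lists covered the unfolded protein response, heat shock, oxidative stress, hypoxia, immediate early genes, glucocorticoid targets, synaptic transmission, histone H3 lysine 4 methylation, histone acetylation enzymes, the response to histone deacetylase inhibitors in cultured cells, nuclear oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, splicing, the proteasome, cholesterol synthesis and interferon. The cell type lists covered CA1, CA2, CA3, dentate granule, cortical, striatal, thalamic and inhibitory neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelial, mural, ependymal, choroid plexus, fibroblast and erythroid cells.

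The genes named in the text follow a rule also fixed before the data were examined. Where at least 10 genes passed the adjusted threshold, the largest and most significant of them would be named, and where fewer passed, the 10 genes of smallest p are named as values. For each list, up to 2 members of smallest p in each direction could be named. A gene that the rule would name is not reported here. Camk2d is always named, while predicted genes, pseudogenes, Xist, Tsix and Y-linked genes are skipped. Kdm5d, Uty, Ddx3y, Zfp26, Hbb-bs, Hba-a1 and the genes named from the adjusted table were chosen after their values were seen.

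The relation between the transgene and drug contrasts was computed over the 500 genes of smallest p in the transgene contrast, with the transgenic vehicle libraries split between the contrasts in 100 random ways. The same was done in 50 permutations of the group labels, but with only 1 split in each. These repeated fits used edgeR without robust fitting, while the fits over other splits of the samples kept robust fitting. The adjusted table was tested with limma on genes with a mean of at least 1 in its own units. Its counts of calls were compared with 100 splits within each pair of groups, the real one included, and with 99 labelings permuted over all 28 libraries. Module means were compared by exact permutation tests, adjusted over 42 tests.

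Alternatives fixed beforehand were RLE scaling, DESeq2 1.42.0, limma voom with quality weights, no low-count filter, a filter of 1 CPM in 9 libraries, fits of only the 2 groups compared, the replicate number as a block, and covariates for Xist, choroid plexus markers or surrogate variables from sva 3.50.0. Each library was also left out in turn in the gene tests. Leaving out each library in turn in the list tests, leaving out the 4 libraries that stand apart, Xist without TMM scaling and the exact tests of lists were chosen after seeing the data. Plots were drawn with matplotlib 3.10.9.

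The tests were tested on simulated data and on real counts thinned to known fold changes. The changed genes were drawn from the 14795 with a mean of at least 1 CPM, so recovery below that level was not measured. Each simulated fit held 67, 67 and 66 genes changed 1.25, 1.5 and 2-fold, and each thinned fit held 200 changed genes. Many genes changed at once loosen the adjusted threshold, so recovery may be lower where few genes change. Simulated counts held no structure of the libraries. Among simulated changes of 1.25-fold in fits of 17009 genes, edgeR recovered 52.2%, 46.3% and 56.7% for the same 3 contrasts, in the same order. At 1.5-fold the shares were 85.1%, 86.6% and 88.1%, and at 2-fold they were 98.5%, 97% and 98.5%. In thinned real counts the shares at 1.5-fold were 90.5%, 84.5% and 88%.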

Results

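CA1 transcriptomes of 28 libraries were compared between 10 wildtype vehicle, 9 transgenic vehicle and 9 transgenic vorinostat libraries. The libraries held 20230085 to 33191857 counts each, with group medians of 23142040 for wildtype vehicle, 25457735 for transgenic vehicle and 23615586 for vorinostat. Totals did not differ past the threshold between groups, with two-sided exact permutation p = 0.509, 0.0926 and 0.68 for transgenic vehicle against wildtype, vorinostat against transgenic vehicle and vorinostat against wildtype.

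Camk2d (ENSMUSG00000053819; GRCm38 chromosome 3, 126596302 to 126846326, plus strand), the endogenous gene of the kinase carried by the transgene, was measured at 78.3 ± 35.3 CPM in wildtype vehicle (SD, n = 10). It was at 63.4 ± 19.8 CPM in transgenic vehicle and at 71.4 ± 22.9 CPM in vorinostat libraries (SD, n = 9 each). The transgene is driven in heart muscle, so its level in brain does not check the genotype labels. The log2 fold changes were -0.30 (SE 0.228) for transgenic vehicle against wildtype, 0.17 (SE 0.234) for vorinostat against transgenic vehicle and -0.13 (SE 0.228) for vorinostat against wildtype. The edgeR adjusted p were 1, 0.701 and 0.791. Without wildtype vehicle 1 the first was -0.164 and the last 0.00839. The second was 0.0549 without vorinostat 5, 0.292 without transgenic vehicle 7 and -0.0257 with surrogate variables, and the last ran from -0.25 to 0.00839 over single libraries left out.

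The libraries differed in mitochondrial and blood transcripts. Mitochondrial genes, which encode subunits of the respiratory chain, held 6.39 to 7.48% of counts in wildtype vehicle 2 and vorinostat 6, 7 and 9, against 2.84 to 4.11% in the other 24 libraries. These 4 libraries also stood apart on the first principal component, at 29.03 to 49.52 against -17.1 to 3.833 for the others. Hemoglobin transcripts, the main transcripts of red blood cells, were at 75.9 to 135 CPM in the 4 libraries and at 16.9 to 52.1 CPM in the other 24. By group, hemoglobin was at 32.7 ± 24.5 CPM in wildtype vehicle (SD, n = 10), 32.8 ± 8.82 in transgenic vehicle and 61.3 ± 34.4 in vorinostat (SD, n = 9 each). It was higher with vorinostat than in transgenic vehicle (exact permutation p = 0.00769), a call that was lost for log2 hemoglobin without the 4 libraries (exact permutation p = 0.0861), and the difference from wildtype did not pass (exact permutation p = 0.0513). The vorinostat libraries among the 4 had the highest hemoglobin of their group, so a smaller difference without them was given in advance. The mitochondrial share did not differ past the threshold in any contrast (exact permutation p = 0.65, 0.166 and 0.235). Xist, the transcript of the inactive X chromosome in females, was high in 6 of 10 wildtype vehicle, 3 of 9 transgenic vehicle and 5 of 9 vorinostat libraries.

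**Figure D1:**
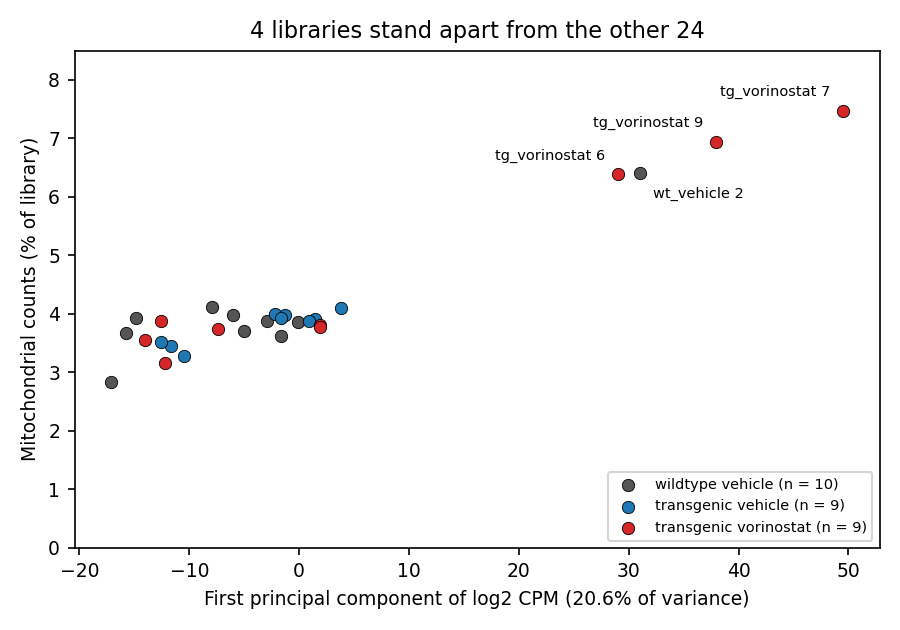
Each point is 1 library, placed by the first principal component of log2 CPM (20.6% of variance) and by the percentage of its counts from mitochondrial genes, with the group given by colour. Wildtype vehicle 2 and vorinostat 6, 7 and 9 lie at 6.39% or more, and the other 24 libraries at 4.11% or less.

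The comparison of transgenic with wildtype vehicle mice asks how the CA1 transcriptome differs in this model of heart failure. Neuronal immediate early genes, which are transcribed within minutes of activity, were higher as a list in transgenic mice, with 24 of 26 measured members positive and a median log2 fold change of 0.178. Egr1 and Egr2, zinc finger transcription factors of this class, had log2 fold changes of 0.40 (SE 0.166) and 0.83 (SE 0.377). Egr1 (ENSMUSG00000038418; chromosome 18, 34859823 to 34864984, plus strand) was at 108 ± 20.3 CPM in wildtype (SD, n = 10) and 143 ± 33.8 CPM in transgenic vehicle libraries (SD, n = 9). The list passed camera's threshold (adjusted p = 1.56e-09), also in every fit that left out 1 library (7.88e-14 to 0.000212). It did not pass with an estimated correlation (adjusted p = 0.862 with an estimated correlation). The list's mean log2 CPM was 4.262 ± 0.201 in wildtype and 4.461 ± 0.259 in transgenic libraries, with 6 of 9 transgenic libraries above the wildtype mean (exact permutation p = 0.0785, adjusted p = 0.783).

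Genes of the unfolded protein response, which act when proteins fold poorly in the endoplasmic reticulum, were higher as a list by a small amount, with 23 of 29 members positive and a median of 0.0329. The co-chaperone Dnajc3 and Sdf2l1 had log2 fold changes of 0.09 (SE 0.0534) and 0.16 (SE 0.0941), while Asns and Chac1 were each at -0.06. Camera gave an adjusted p of 0.00589 (adjusted p = 0.862 with an estimated correlation), with 8 of 9 transgenic libraries above the wildtype mean (exact permutation p = 0.0316, adjusted p = 0.783). The call was lost without transgenic vehicle 6 (adjusted p = 0.0527). Nuclear genes of oxidative phosphorylation, the subunits of the respiratory chain and ATP synthase, were lower as a list (43 of 48 negative, median -0.028, adjusted p = 0.033, and adjusted p = 0.862 with an estimated correlation). Ndufs7 and Cycs were at -0.09 and -0.14, and Atp5g1 and Uqcrb at 0.05 and 0.04, and the exact permutation p of the list mean was 0.662 (adjusted p = 0.875). Wildtype vehicle 2, with a mitochondrial share of 6.41%, is among the controls, and the list pointed upwards without it (adjusted p = 0.474) and without the 4 libraries that stand apart (0.137). The call was also lost without any 1 of transgenic vehicle 1, 3, 4, 6, 8 and 9 and wildtype vehicle 1 and 5 (0.0513 to 0.34).

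Lists of markers of cells outside the CA1 pyramidal layer also passed camera between these groups. Oligodendrocyte markers, the genes of myelin-forming cells, were all positive (11 of 11; Ugt8a 0.15, Mobp 0.17; adjusted p = 0.00234). Dentate granule markers were positive in 6 of 7 (Prox1 0.25, Tdo2 0.50, C1ql2 -0.05; adjusted p = 0.00816), choroid plexus markers in 7 of 8 (Kl 0.27, Aqp1 0.39, Prlr -0.37; adjusted p = 0.00941) and fibroblast markers in 7 of 8 (Col3a1 0.50, Igf2 0.26, Dcn -0.10; adjusted p = 0.033). Thalamic markers were negative in 5 of 6, with Calb2 at -0.38 (SE 0.164) and Prkcd at -0.25 (SE 0.11; adjusted p = 0.033 for the list). Each of these 5 lists had an adjusted p of 0.862 with an estimated correlation. By exact permutation of the list means, p was 0.407 for oligodendrocyte, 0.218 for dentate, 0.157 for choroid plexus, 0.221 for fibroblast and 0.296 for thalamic markers (adjusted p = 0.831 each). Transgenic libraries lay on the side of the call in 5 of 9 for oligodendrocyte, 6 of 9 for fibroblast and 7 of 9 for each of the other lists. The oligodendrocyte call was lost without transgenic vehicle 5 (0.055) or 6 (0.255) or wildtype vehicle 10 (0.111), and the choroid plexus call without transgenic vehicle 5 (0.0652) or 9 (0.142). The dentate call was lost without transgenic vehicle 3 (0.0574) or 9 (0.13) or wildtype vehicle 1 (0.0663). The fibroblast call was lost without any 1 of transgenic vehicle 1, 3 and 7, vorinostat 6 and wildtype vehicle 2, 7, 8, 9 and 10 (0.0529 to 0.374). The thalamic call was lost without any 1 of transgenic vehicle 1, 2, 5, 8 and 9 and wildtype vehicle 1, 6 and 8 (0.0529 to 0.307). Without the 4 libraries that stand apart the dentate (0.0541) and fibroblast (0.184) calls were lost, and with surrogate variables all 5 were (0.0769 to 0.365). A covariate for Xist ended the dentate (0.143) and thalamic (0.199) calls, and one for choroid plexus markers ended the dentate and oligodendrocyte (0.0551 each) and fibroblast (0.321) calls.

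No single gene passed between transgenic and wildtype vehicle libraries. Bcl6b, a transcriptional repressor (ENSMUSG00000000317; chromosome 11, 70224128 to 70229798, minus strand), had the smallest p, with a log2 fold change of 0.52 (SE 0.147) from 1.18 to 1.7 CPM. Hells, a helicase that remodels chromatin (ENSMUSG00000025001; chromosome 19, 38930915 to 38971051, plus strand), was at -0.27 (SE 0.0839), from 4 to 3.32 CPM. Hhip, which binds hedgehog ligands, and the adhesion receptor Adgrg6 were at 0.50 and 0.49, and the repressor Tgif1 and the apoptosis regulator Pawr at 0.40 and 0.45. The potassium channel gene Kcnk2 was at 0.15 and the tubulin regulator Tppp3 at 0.22, while the anion transporters Slc26a8 and Slc26a4 were at -0.24 and -0.23. All 10 had an adjusted p of 1. By edgeR 0 of 17009 genes passed, 227 had an unadjusted p under 0.05 where 850 are due by chance, and the smallest p was 0.00133. DESeq2 and voom also called 0, with 358 and 652 genes at an unadjusted p under 0.05, and 0 list members passed over all genes and 0 adjusted over the list alone. The log2 fold change was under 0.5 in size for 99.56% of genes.

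The comparison of vorinostat with vehicle in transgenic mice asks what inhibiting histone deacetylases changes in the diseased animals. Erythroid genes were higher as a list with vorinostat, in 4 of 4 members with a median log2 fold change of 0.851. Alas2, the first enzyme of heme synthesis in red blood cell precursors (ENSMUSG00000025270; chromosome X, 150547375 to 150570638, plus strand), went from 2.2 ± 0.558 to 3.88 ± 1.19 CPM (SD, n = 9 each), a log2 fold change of 0.81 (SE 0.209). The hemoglobin chain gene Hbb-bt (ENSMUSG00000073940; chromosome 7, 103812524 to 103813996, minus strand) was at 0.96 (SE 0.281), from 4.09 to 7.98 CPM, with reads that near-identical hemoglobin genes may share. The list's mean log2 CPM was 2.628 ± 0.42 in vehicle and 3.407 ± 0.587 in vorinostat libraries, and 9 of 9 vorinostat libraries lay above the vehicle mean (exact permutation p = 0.00169, adjusted p = 0.177). Camera gave an adjusted p of 0.000449 (adjusted p = 0.862 with an estimated correlation), and no single left-out library ended the call. Among the members 4 passed adjusted over the list alone and 0 over all genes tested. Vorinostat 6, 7 and 9 had hemoglobin of 75.9 to 135 CPM, and without the 4 libraries that stand apart the list still passed camera (adjusted p = 2.02e-06). The log2 difference in hemoglobin was then 0.35 instead of 0.773, and its call was lost (exact permutation p = 0.0861 instead of 0.00773). The vorinostat libraries left out were the highest in hemoglobin of their group, so a smaller difference was given in advance.

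Endothelial markers, genes of the vessel lining, were positive in 8 of 10 members, with Itm2a at 0.32 (SE 0.0834), Slco1a4 at 0.37 (SE 0.113) and Cdh5 at -0.18. The adjusted p was 0.0291 by camera (adjusted p = 0.862 with an estimated correlation), and 2 members passed adjusted over the list alone and 0 over all genes. The call was lost without any 1 of transgenic vehicle 2, 7 and 8 and vorinostat 1, 3 and 5 (0.0519 to 0.0943). The exact permutation p of the list mean was 0.176 (adjusted p = 0.831). Without the 4 libraries that stand apart the adjusted p by camera was 0.00106.

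Markers of CA2 pyramidal neurons, which lie beside CA1, were lower as a list with vorinostat, in 5 of 6 members with a median of -0.328. The kinase gene Map3k15 was at -0.75 (SE 0.279) and the calcium channel subunit gene Cacng5 at -0.27 (SE 0.11), while Pcp4 was at 0.07. The adjusted p was 0.0155 by camera (adjusted p = 0.862 with an estimated correlation), and 7 of 9 vorinostat libraries lay below the vehicle mean (exact permutation p = 0.0189, adjusted p = 0.661). The call was lost without vorinostat 3 (0.0591) or 4 (0.0537) and with Xist as a covariate (0.0592), and without the 4 libraries that stand apart it was at 1.2e-05. Dentate granule markers were negative in 7 of 7, with the transcription factors Prox1 at -0.43 and Glis3 at -0.37 (adjusted p = 0.0396, and adjusted p = 0.862 with an estimated correlation), and an exact permutation p of 0.074 (adjusted p = 0.783). That call was lost without any 1 of transgenic vehicle 3, 7, 8 and 9 and vorinostat 1, 2, 3, 4, 5, 6 and 7 (0.0524 to 0.167) and with covariates for Xist (0.188), surrogate variables (0.144) or choroid plexus markers (0.0748), and it was at 0.00949 without the 4 libraries. Dentate markers were called higher in transgenic against wildtype vehicle, and both contrasts share the transgenic vehicle libraries, which alone favours opposite signs.

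Immediate early genes were lower as a list with vorinostat, with 23 of 26 negative. This contrast shares the transgenic vehicle libraries with that against wildtype, where the list was called higher, and sharing alone favours opposite signs. Egr4 was at -0.40 (SE 0.186) and Fosb at -0.27 (SE 0.144), and Homer1 and Dusp6 were at 0.05 and 0.06. The adjusted p was 0.0234 by camera (adjusted p = 0.862 with an estimated correlation), with 6 of 9 vorinostat libraries below the vehicle mean (exact permutation p = 0.306, adjusted p = 0.831). The call was lost without the 4 libraries that stand apart (0.807), with surrogate variables (0.353) and without any 1 of transgenic vehicle 1, 2 and 8 and vorinostat 3, 5, 6, 8 and 9 (0.054 to 0.17). Histone deacetylases and acetyltransferases, the enzyme families that vorinostat acts on and their counterparts, were negative in 17 of 23, with Kat7 at -0.09, Hdac7 at -0.29, Kat8 at 0.07 and Hdac2 at 0.11. The adjusted p was 0.0408 by camera (adjusted p = 0.862 with an estimated correlation), and the exact permutation p was 0.0673 (adjusted p = 0.783). It was lost without the 4 libraries (0.847) and without any 1 of transgenic vehicle 2, 3, 6 and 8 and vorinostat 6, 7 and 9 (0.0519 to 0.0922).

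Lists of respiration, protein synthesis and turnover, RNA processing and synapses also passed, and vorinostat 6, 7 and 9 had a high mitochondrial share (6.39 to 7.48%). Nuclear oxidative phosphorylation genes were positive in 42 of 48 (Ndufs1 0.15, Uqcrc2 0.17, Uqcrc1 -0.09, Ndufv1 -0.05; adjusted p = 0.00115). They were called lower in transgenic against wildtype vehicle, a contrast that shares the transgenic vehicle libraries with this one. Proteasome subunits, which degrade tagged proteins, were positive in 26 of 29 (Psmc6 0.26, Psma3 0.18, Psmd11 -0.02; adjusted p = 0.000577). Ribosomal proteins were positive in 40 of 44 (Rpl38 0.34, Rpl5 0.21, Rpl28 -0.13; adjusted p = 0.0151). In each of these 3 lists 3 of 9 vorinostat libraries lay above the vehicle mean, and those were vorinostat 6, 7 and 9. Without the 4 libraries that stand apart all 3 pointed downwards, with adjusted p = 2.02e-06 for oxidative phosphorylation, 0.00291 for the proteasome and 5.3e-09 for ribosomal proteins. That removal takes out the vorinostat libraries above the vehicle mean and no transgenic vehicle library, so a downward shift was favoured in advance. These p-values are therefore no support for a lower level with vorinostat. Transgenic vehicle 5, high for oxidative phosphorylation (6.79 mean log2 CPM) and ribosomal proteins (4.66), stayed in. Mitochondrially encoded genes were positive in 7 of 7 tested of 13 listed (mt-Nd5 0.27, mt-Nd2 0.32; adjusted p = 0.00465), with 7 of 9 vorinostat libraries above the vehicle mean, and pointed downwards without the 4 libraries (0.479). Splicing genes were positive in 28 of 37 (Clk4 0.22, Hnrnph1 0.16, Srsf4 -0.10, Snrnp70 -0.12; adjusted p = 0.0116), also with 7 of 9 vorinostat libraries above the vehicle mean, and did not pass without the 4 (0.606). Synaptic genes were negative in 26 of 38 (Vamp2 -0.16, Nlgn3 -0.15, Gria2 0.19, Creb1 0.15; adjusted p = 0.0234), with 4 of 9 vorinostat libraries below the vehicle mean, and pointed upwards without the 4 (0.0682). All 6 lists had an adjusted p of 0.862 with an estimated correlation, and their exact permutation p ran from 0.14 to 0.481 (adjusted p = 0.831 each). Single libraries that ended a call were vorinostat 7 for oxidative phosphorylation (0.0674) and transgenic vehicle 5 for splicing (0.055). Vorinostat 6 (0.177), 7 (0.227) and 9 (0.17) ended it for ribosomal proteins, and any 1 of transgenic vehicle 1, 8 and 9 and vorinostat 6, 7 and 9 ended it for synaptic genes (0.0533 to 0.126). Surrogate variables ended the ribosomal (0.136) and splicing (0.414) calls.

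Genes known to rise with histone deacetylase inhibitors in cultured cells did not pass as a list, with a median of -0.0149 over 11 members and an adjusted p of 0.949. Glrx, a glutaredoxin that reduces protein disulfides (ENSMUSG00000021591; chromosome 13, 75839868 to 75850154, plus strand), passed adjusted over the list alone (p = 0.0238, edgeR) but not over all genes. It went from 22.5 ± 1.03 to 26.9 ± 4.48 CPM (SD, n = 9 each), a log2 fold change of 0.26 (SE 0.0765). Hist1h2bc was at 0.08, Gsn, an actin-severing protein, at -0.14 and the cell cycle inhibitor Cdkn1a at -0.22. The same list had an adjusted p of 0.965 in transgenic against wildtype vehicle and 0.936 in vorinostat against wildtype, with medians of 0.00416 and -0.00734.

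Single genes did not pass between vorinostat and vehicle in transgenic mice. Igfbp4, a binding protein of insulin-like growth factors (ENSMUSG00000017493; chromosome 11, 99041244 to 99054392, plus strand), was at 103 ± 5.99 CPM in vehicle and 78 ± 11.4 CPM in vorinostat libraries (SD, n = 9 each), a log2 fold change of -0.40 (SE 0.0801). It was lower than the vehicle mean in 9 of 9 vorinostat libraries (edgeR p = 2.37e-05, adjusted p = 0.344). DESeq2 called it (adjusted p = 0.0483), as did edgeR without vorinostat 3 (0.0331). Prdm8, a transcriptional regulator of neurons (ENSMUSG00000035456; chromosome 5, 98167198 to 98188991, plus strand), was at 15.1 ± 3.69 and 9.55 ± 2.58 CPM, a log2 fold change of -0.66 (SE 0.153), lower in 9 of 9. The polarity gene Crb2 was at -0.46, Eva1c at -0.51 and Sypl2 at -0.40. Dgat2, an enzyme of triglyceride synthesis, was at -0.24, and Slc30a3, the zinc transporter of synaptic vesicles, at -0.32. Hells was at 0.36 (SE 0.0857), from 3.32 to 4.28 CPM, a value that shares the transgenic vehicle libraries with its value against wildtype. The DNA ligase gene Lig4 was at 0.27. All 10 genes of smallest p, Alas2 among them, had an adjusted p of 0.344. By edgeR 0 of 17009 genes passed, while 2450 had an unadjusted p under 0.05 against 850 due by chance. That count was 664 without the 4 libraries that stand apart, and voom gave 1109 with 0 called, DESeq2 calling only Igfbp4.

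The comparison of vorinostat-treated transgenic mice with wildtype vehicle mice asks which differences from healthy littermates are present under treatment. Erythroid genes were again higher as a list, in 4 of 4 members with a median of 0.894. Alas2 was at 0.89 (SE 0.205), from 2.11 to 3.88 CPM, and Hbb-bt at 0.96 (SE 0.274). Camera gave an adjusted p of 1.06e-05 (adjusted p = 0.862 with an estimated correlation), and the exact permutation p of the list mean was 0.00521 (adjusted p = 0.273), with 9 of 9 vorinostat libraries above the wildtype mean. Wildtype vehicle 2, with hemoglobin of 101 CPM, is among the controls. Without it edgeR called Alas2 (adjusted p = 0.00896), Hbb-bt (0.0162) and Hbb-bs (0.0316), and without the 4 libraries that stand apart the list was at 9.8e-19. In this list 4 members passed adjusted over the list alone and 0 over all genes tested. Among endothelial markers 2 did, Itm2a at 0.28 and Slco1a4 at 0.31, as did Adm of the hypoxia list and the thalamic marker Prkcd at -0.40 (SE 0.111), though these 3 lists did not pass.

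CA2 markers were lower as a list than in wildtype in 6 of 6 members, with Cacng5 and Rgs14, a regulator of G protein signalling, each at -0.25 (adjusted p = 0.033, and adjusted p = 0.862 with an estimated correlation), and an exact permutation p of 0.0762 (adjusted p = 0.783). That call was lost without any 1 of vorinostat 1, 3, 4 and 5 and wildtype vehicle 4 and 9 (0.0738 to 0.103), and it was at 1.2e-05 without the 4 libraries that stand apart. Splicing genes were positive in 29 of 37, with the kinases Clk4 at 0.24 and Prpf4b at 0.19 (adjusted p = 0.00115, and adjusted p = 0.862 with an estimated correlation). They were at 0.072 without the 4 libraries, and the exact permutation p was 0.0894 (adjusted p = 0.783). Proteasome genes were positive in 25 of 29 (adjusted p = 0.00941), oxidative phosphorylation genes in 39 of 48 (0.0291) and mitochondrially encoded genes in 7 of 7 (0.0396), and synaptic genes were negative in 29 of 38, with Vamp2 at -0.18 (0.011). In the first 3 of these lists 3 of 9 vorinostat libraries lay above the wildtype mean. Each of the 4 lists had an adjusted p of 0.862 with an estimated correlation, and their exact permutation p ran from 0.239 to 0.476 (adjusted p = 0.831 each). Without the 4 libraries that stand apart all 4 turned direction, with adjusted p = 0.106 for the proteasome, 0.00121 for oxidative phosphorylation, 0.479 for mitochondrially encoded and 0.88 for synaptic genes. Those libraries were chosen on these data by mitochondrial share, and 3 of the 4 are vorinostat libraries, so a turn was favoured in advance. The proteasome call was lost without vorinostat 6 (0.091), 7 (0.214) or 9 (0.101), and the synaptic call without vorinostat 6 (0.0785) or 9 (0.0665) or wildtype vehicle 7 (0.0638). The oxidative phosphorylation call was lost without any 1 of vorinostat 6, 7 and 9 and wildtype vehicle 3, 7, 8, 9 and 10 (0.0582 to 0.675). The mitochondrially encoded call was lost without any 1 of vorinostat 6, 7 and 9 and wildtype vehicle 1, 4, 6, 7 and 8 (0.0503 to 0.231). With surrogate variables all 4 calls were lost, at 0.644 for the proteasome and 0.0503 for oxidative phosphorylation, which both turned direction, 0.79 for mitochondrially encoded and 0.211 for synaptic genes. With choroid plexus markers as a covariate oxidative phosphorylation (0.0512) and mitochondrially encoded genes (0.0551) did not pass.

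Single genes did not pass between vorinostat and wildtype vehicle libraries. Adm, which encodes the vasodilator peptide adrenomedullin (ENSMUSG00000030790; chromosome 7, 110627661 to 110629820, plus strand), had the smallest p, at 1.07 CPM in wildtype and 1.63 CPM in vorinostat libraries. Its log2 fold change was 0.58 (SE 0.123), higher than the wildtype mean in 9 of 9 libraries (edgeR p = 4.91e-05, adjusted p = 0.385). Voom called Adm (adjusted p = 0.0323) and Alas2 (0.0403), and edgeR called Adm without wildtype vehicle 5 (0.0184). The peptide transporter gene Slc15a2 was at 0.33, the lipid transporter gene Abca9 at 0.30, Slc35g2 at 0.31 and the endosomal gene Zfyve16 at 0.28. Zfp607b was at 0.22, Desi2 at 0.21 and Tmem260 at 0.20, and all 10 genes of smallest p had an adjusted p of 0.385. By edgeR 0 of 17009 genes passed and 2142 had an unadjusted p under 0.05. That count was 721 without the 4 libraries that stand apart and 3764 without wildtype vehicle 2, while voom gave 1025 with the 2 genes above called and DESeq2 called 0.

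**Figure D2:**
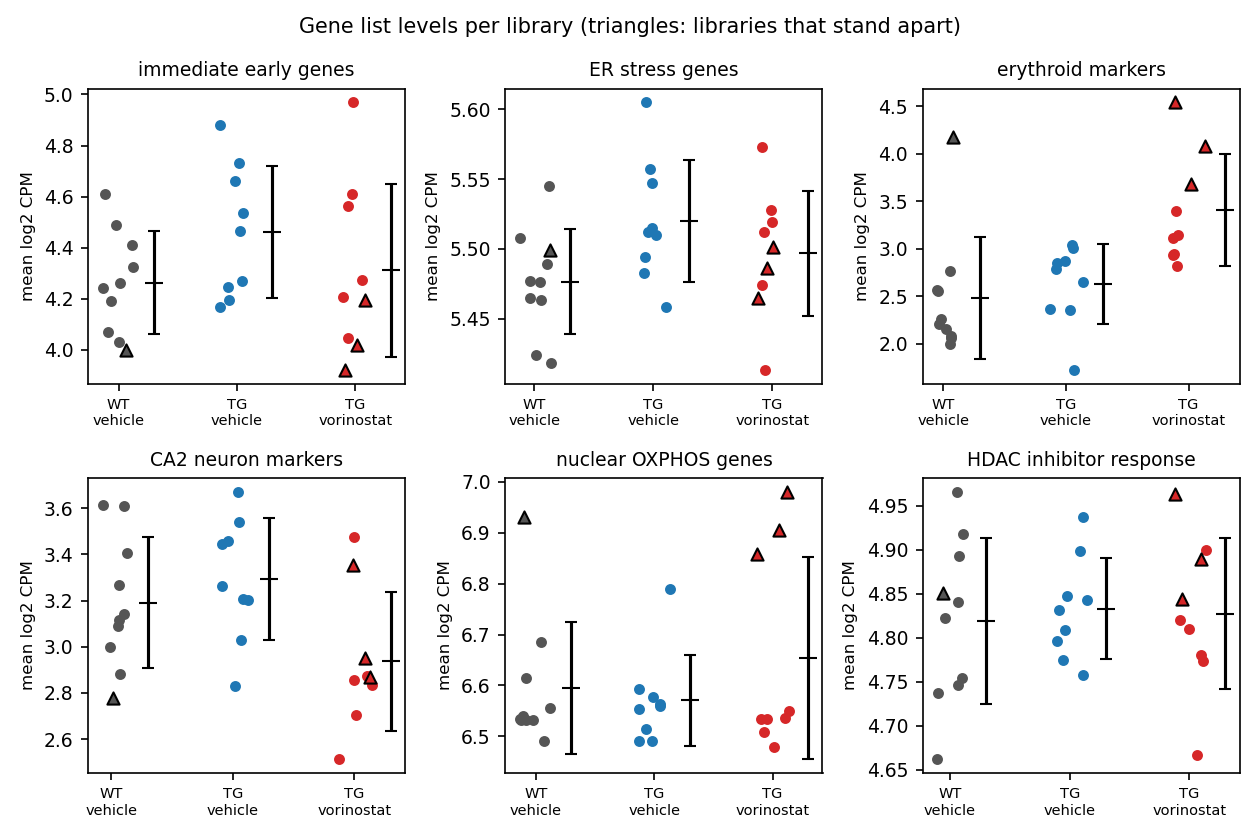
Each panel shows 1 gene list, with the mean log2 CPM of its genes per library on the vertical axis, a point per library by group, triangles for the 4 libraries that stand apart, and bars for the group mean ± SD. Erythroid genes averaged 2.628 ± 0.42 in transgenic vehicle and 3.407 ± 0.587 in vorinostat libraries.

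Whether vorinostat shifted genes against the direction of the transgene was asked over the 500 genes of smallest p in the transgene contrast. With the transgenic vehicle libraries split between the contrasts, a median of 46.8% of these genes had opposite signs over 100 splits (5th to 95th percentile 33.1 to 57.6%). Permuted labels, with a single split each, gave a median of 50.4% (19.9 to 80.5%), a range too wide to show a modest shift. The observed value was 83% when the contrasts shared the transgenic vehicle libraries, against 91.5% (68.7 to 99%) in permuted labels that shared them. The covariance of log2 fold changes was 5.32e-05 with split libraries against 0.000247 in permuted labels, and -0.00713 with shared libraries against -0.00833. The opposite-sign share was thus not above that of permuted labels in either form. Immediate early genes did not pass in vorinostat against wildtype (camera adjusted p = 0.639), and they passed upwards there without the 4 libraries that stand apart (0.00279).

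None of the list calls held with an estimated correlation, and none of the exact permutation tests of list means passed after adjustment (smallest adjusted p = 0.783, 0.177 and 0.273 in the 3 contrasts). Camera called 8, 12 and 7 of 35 lists. Several lists passed in no contrast. Camera's adjusted p for transgenic vehicle against wildtype, vorinostat against transgenic vehicle and vorinostat against wildtype were 0.16, 0.594 and 0.16 for heat shock, 0.865, 0.412 and 0.323 for oxidative stress, and 0.57, 0.865 and 0.599 for hypoxia. In the same order, they were 0.0803, 0.464 and 0.888 for glucocorticoid targets, 0.271, 0.109 and 0.317 for histone H3 lysine 4 methylation, 0.287, 0.286 and 0.609 for cholesterol synthesis, and 0.159, 0.325 and 0.839 for interferon genes. Among neurons they were 0.714, 0.16 and 0.0803 for CA1, 0.949, 0.464 and 0.464 for CA3, 0.316, 0.759 and 0.865 for cortical, 0.226, 0.2 and 0.535 for striatal, and 0.16, 0.865 and 0.341 for inhibitory markers. Astrocyte markers were at 0.169, 0.65 and 0.865, oligodendrocyte precursor markers at 0.865, 0.782 and 0.839, and microglial markers at 0.109, 0.109 and 0.464. Mural markers were at 0.325, 0.79 and 0.865 and ependymal markers at 0.48, 0.16 and 0.286.

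In the authors' deposited table of adjusted values, limma called 188 genes between transgenic and wildtype vehicle (112 higher and 76 lower). It called 46 between vorinostat and transgenic vehicle (29 higher and 17 lower) and 2443 between vorinostat and wildtype (1713 higher and 730 lower). These counts were 1049, 1 and 53 without the 4 libraries that stand apart. The acyl-CoA thioesterase gene Acot3 led the first contrast (-0.315 in the table's log units, adjusted p = 0.000396), and the zinc finger gene Zfp93 the next (0.209, adjusted p = 0.0328). Mycbp, a binding partner of Myc, the kainate receptor gene Grik1 and Adm led vorinostat against wildtype, at 0.298, 0.273 and 0.391 (adjusted p = 8.74e-05 each, limma). Limma on log2 CPM of the counts called 0 genes in each contrast. Of the called genes also tested in the counts, 24 of 185, 40 of 45 and 1304 of 2424 had an unadjusted p under 0.05 there, in the same libraries, so this is no independent check. The median residual SD was 0.116 in the table and 0.175 in the counts, and Xist lay between 17.25 and 18.29 in every column of the table, while in the counts it was at 2.049 CPM or less or at 663.8 CPM or more. The terms of the table's model were not given in the sources used here, and if the group labels were among them, neither limma nor a permutation of labels gives a valid p on the table. With that limit, CA1 markers were lower in the table in transgenic than in wildtype vehicle (exact permutation adjusted p = 0.0494) and in vorinostat than in wildtype (-0.192, 0.0224). The same exact permutation test of the counts gave adjusted p = 0.936 and 0.831 for them, and camera 0.714 and 0.0803. Erythroid genes were higher in the table in vorinostat than in wildtype (0.697, 0.0298, against 0.273 by the same test of the counts). Between vorinostat and transgenic vehicle, histone acetylation enzymes differed by -0.0491 (0.0173), and endothelial (0.0173), erythroid (0.0415) and hypoxia (0.0494) lists also passed. The 14 deposited coexpression modules, made on these or overlapping samples, gave 0 calls from the counts (smallest exact permutation adjusted p = 0.6, 0.332 and 0.332) and 2, 4 and 2 calls from the table, under the same limit.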

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

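Of the tests in this part, the gene length trend, the endothelial covariate and the adjustment with protected labels were chosen before their results were seen, and the others only after. For the test of the adjusted table without 4 libraries, the bound that would have excluded the explanation was moved after the result was seen, from the range of the random removals to their median, which turned an exclusion into an open result.

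Wildtype vehicle 2 and vorinostat 6, 7 and 9 stood apart on the first principal component and in their mitochondrial share. Across genes wildtype vehicle 2 deviated like the other 3 (r = 0.694, against -0.179 to 0.128 for the other 24 libraries, with genes not independent replicates). The 4 share high scores on that component of the same values, so a high r was given in advance and is no further support. Blood in the sample is argued against as the whole cause, since hemoglobin gained 0.117 to 0.399% as many CPM as mitochondrial genes did. Hemoglobin may be undercounted, since the treatment of reads matching several genes is not known. A gene length trend of the kind that RNA quality can give stays open, with a median rho of -0.251 over the 4 libraries (-0.301 to -0.21) inside the range of the other 24 (-0.404 to 0.227). Vorinostat, the biological explanation the design offers, also cannot be told apart, since 3 of 9 vorinostat and 1 of 19 vehicle libraries stood apart (two-sided Fisher's exact p = 0.0841) and the samples are too few to decide.

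Hemoglobin and Alas2 were higher in vorinostat than in transgenic vehicle libraries, by 0.773 on the log2 scale for hemoglobin (exact permutation p = 0.00773). More vessel tissue, as far as the endothelial markers measure it, is argued against, since 0.975 of the difference was left with them as a covariate (0.754, SE 0.296). The markers' mean log2 CPM was 3.954 ± 0.177 in transgenic vehicle and 4.055 ± 0.126 in vorinostat libraries (SD, n = 9 each). A covariate that measures vessels poorly would also leave most of the difference. More blood in the tissue may explain it, because Alas2 and hemoglobin differed by like factors (difference of their log2 ratio -0.166, SE 0.162, exact permutation p = 0.32). The 4 libraries that stand apart stay open as a cause, since without them the difference was 0.35 (exact permutation p = 0.0861) with 6 vorinostat libraries left. That fit cannot decide, because the vorinostat libraries left out had the highest hemoglobin of their group (75.9 to 135 CPM, against at most 52.1 in the others). A smaller difference was thus given in advance. An effect of vorinostat on red blood cells themselves was not tested apart from the amount of blood.

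The adjusted table called 2443 genes between vorinostat and wildtype where the counts called 0. An adjustment that protects the group labels could make such calls, because removing 5 surrogate variables in this way gave called genes in 15 of 20 permuted labelings (median 14.5, highest 196, real labels 83), and 0 of 20 without it. These counts are below 2443, but they come from 1 assumed setting, so they set no limit on what the table's own adjustment could give. Removal of the sex difference is argued against, since log2 CPM with a term for high or low Xist called 0 genes. The 4 libraries that stand apart stay open, since without them 53 genes were called and 1 of 20 random removals of as many libraries gave as few (28 to 5264, median 1230.5), and no biological explanation was tested.

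For splits of the samples, 100 were used in each contrast, the real one among them. The counts of splits that reach a real value therefore include the real one. In the adjusted table, whether chance can be excluded stays open, since the group labels may have been in the table's model: with an adjustment that protects them, 15 of 20 permuted labelings gave calls. Of the splits, 2 gave as many as the real 188 genes between transgenic and wildtype vehicle (highest other 718), and 1, the real one, gave as many as 46 between vorinostat and transgenic vehicle (highest other 0) and as 2443 between vorinostat and wildtype (highest other 1070). The terms of that model were not given in the sources used here, and with the labels among them other splits would fall below the real one without any effect. The same limit holds for labelings permuted across all 28 libraries. Over 99 of these, 0 reached 188 (highest 1) and 0 reached 2443 (highest 1), while 1 reached 46, with 3002 genes, which points to a structure of the samples.

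In the counts, the real number of genes past the adjusted threshold was 0 in each contrast, so 100 of 100 splits had to reach it and their number says nothing about chance. The highest other counts were 0, 6 and 1608, and the last points to a structure of the samples in vorinostat against wildtype. Chance could not be excluded for the counts of genes at an unadjusted p under 0.05 or for the numbers of lists called. For genes at an unadjusted p under 0.05, 82 splits reached the real 227 for transgenic against wildtype vehicle (highest other 1942), 13 reached 2450 for vorinostat against transgenic vehicle (highest other 3887) and 14 reached 2142 for vorinostat against wildtype (highest other 5611). The 1942 genes of 1 split point to such a structure as well, as do the 718 genes in the adjusted table. For gene lists past camera's threshold, 52 splits reached the real 8 (highest other 14), 16 reached 12 (highest other 14) and 85 reached 7 (highest other 17).

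Single libraries lay far from the rest of their group in 13 of 150 group values examined, where 7.5 are due by chance. Wildtype vehicle 5 had 33200000 counts and 25800 genes detected. Wildtype vehicle 2 had a mitochondrial share of 6.41%, hemoglobin of 101 CPM and a log2 CPM of Alas2 of 2.29. In mean log2 CPM of lists it was at 6.93 for nuclear oxidative phosphorylation, 12.6 for mitochondrially encoded genes, 6.36 for the proteasome, 4.17 for erythroid genes and, at the low end, 3.36 for endothelial markers. Transgenic vehicle 5 was at 6.79 for nuclear oxidative phosphorylation and 4.66 for ribosomal proteins, and transgenic vehicle 7 had the low log2 CPM of Alas2, 0.131.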

How the results depend on the processing

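The settings without the 4 libraries that stand apart, the exact tests of lists, the list fits with 1 library left out and Xist without TMM scaling were chosen after seeing the data. Those 4 libraries were picked on these same data and 3 of them are vorinostat libraries, so some changes without them were favoured in advance. The cause was not tested for any change below, except that fewer libraries enter where some are left out. The 0 genes called became 1 with DESeq2 and 3 with the Xist covariate without TMM scaling (Kdm5d, Uty and Ddx3y) between vorinostat and transgenic vehicle, and 2 with voom between vorinostat and wildtype. Kdm5d, Uty and Ddx3y are Y-linked, and the groups are of mixed sex. Their log2 fold changes were 0.973, 1.27 and 1.2 with that covariate, against -0.271, -0.0247 and -0.0838 without it. With 1 library left out the counts ran from 0 to 0, 0 to 1 and 0 to 3 for transgenic against wildtype vehicle, vorinostat against transgenic vehicle and vorinostat against wildtype. Counts at an unadjusted p under 0.05 ran over 1.5 times from the values given, to 1039 without a filter and 1052 with surrogate variables (transgenic against wildtype vehicle), 3896 with Xist (vorinostat against transgenic vehicle) and 1423 with only 2 groups (vorinostat against wildtype). In that order, they were 412, 664 and 721 without the 4 libraries. Singly, vorinostat 6, 7 and 9 moved the vorinostat against transgenic vehicle count to 1296, 1062 and 1248, and the vorinostat against wildtype count to 1251, 1066 and 1293, where wildtype vehicle 5 gave 1278.

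Camk2d turned direction with surrogate variables (-0.0257, vorinostat against transgenic vehicle) and without wildtype vehicle 1 (0.00839, vorinostat against wildtype). With 1 library left out it ran from -0.427 to -0.164, 0.0549 to 0.292 and -0.25 to 0.00839. The list calls fell to 0, 0 and 0 with an estimated correlation and with exact permutation. With 1 library left out they ran from 4 to 12, 7 to 13 and 3 to 10. They were 5 and 4 without transgenic vehicle 1 and 9, 7 without transgenic vehicle 8 or vorinostat 6 or 7, and 4 and 3 without wildtype vehicle 7 and vorinostat 6 in the 3 contrasts. With surrogate variables, oxidative phosphorylation (adjusted p = 0.0503) and the proteasome (0.644) turned direction between vorinostat and wildtype. Without the 4 libraries, oxidative phosphorylation turned in each contrast (0.137, 2.02e-06 and 0.00121), as did synaptic (0.0682 and 0.88), mitochondrially encoded (0.479 and 0.479) and proteasome genes (0.00291 and 0.106) in the latter 2, and ribosomal proteins between vorinostat and transgenic vehicle (5.3e-09). Without wildtype vehicle 2, oxidative phosphorylation turned between transgenic and wildtype vehicle (0.474; 7.48e-06 to 0.474 over libraries left out). Over all list calls, 113 settings gave the same call, 91 lost it and 12 turned it, and with 1 library left out these were 648, 107 and 1. Named genes kept direction and side in 386 settings and newly passed in 3.

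The opposite-sign share was 83% with shared transgenic vehicle libraries, 47.4% with RLE scaling and 43.6% without the 4 libraries. The adjusted table gave 398 genes without a filter for transgenic against wildtype vehicle, and 1049, 1 and 53 without the 4 libraries. The numbers of the titles do not pair the samples: 7 of 27 same-numbered pairs had a correlation over 0.1, 3 of 28 libraries correlated best with their own number, and for the numbers of the descriptions these were 7 of 26 and 0 of 28. With the replicate block 1 gene (Zfp26, chosen after its value was seen) was called between vorinostat and wildtype, and 4 lists passed there, those of oxidative phosphorylation (0.193), mitochondrially encoded (0.0743) and synaptic genes (0.0853) being lost. The block also ended the oligodendrocyte (0.161) and fibroblast (0.0853) calls between transgenic and wildtype vehicle, and no other list call. A pseudocount of 0.1 was not run because the table is on a log scale, and the opposite-sign share of called genes was not run because 0 were called. Depth limits genes near 1 CPM, such as Bcl6b and Adm.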

Other observations

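The tests without the 4 libraries that stand apart were chosen only after the data were seen. Without the 4 libraries, ependymal markers, genes of the ciliated cells that line the ventricles, were lower as a list with vorinostat than in transgenic vehicle (camera adjusted p = 0.000354) and than in wildtype (0.00318). In all 28 libraries they did not pass (0.16 and 0.286 by camera, exact permutation p = 0.191 and 0.17), with Foxj1, the master regulator of motile cilia, at -0.43 (SE 0.176). Of 6 listed ependymal markers 4 were tested, and their level was low. Their mean log2 CPM was 0.355 ± 0.562 in wildtype vehicle, 0.41 ± 0.784 in transgenic vehicle and -0.109 ± 0.833 in vorinostat libraries (SD). Oxidative stress genes (0.00949), astrocyte markers (0.00949) and oligodendrocyte markers (0.0159) were also lower with vorinostat than in transgenic vehicle without the 4 libraries, and genes of histone H3 lysine 4 methylation were higher (0.0314). In transgenic against wildtype vehicle, erythroid genes (3.8e-06), astrocyte markers (0.0285) and heat shock genes (0.0467) were then higher, and endothelial markers (0.017) and synaptic genes (0.0316) lower. Immediate early genes then passed in vorinostat against wildtype as well, upwards (0.00279). Neither estimated correlations nor exact permutation tests were used for these fits, and none of the list calls of all 28 libraries held with estimated correlations.

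Among genes of lists that did not pass between vorinostat and transgenic vehicle, the interferon-induced gene Ifit1 was at 0.58 (SE 0.187) and the microglial receptor gene P2ry12 at 0.34 (SE 0.13), with edgeR adjusted p = 0.344 each. Lig4, a ligase that joins broken DNA ends, was called in the adjusted table (0.241 in the table's log units, limma adjusted p = 0.0373), and in the counts its adjusted p was 0.344.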
